A study of Homo sapiens with 117 samples.

How the data were processed

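The source is the authors' deposited table of TPM for 19207 gene symbols and 117 libraries, with the TPM values made by the authors before deposit as transcript abundance scaled to the same total in each library. Per the labels' protocols RNA was extracted with TRIzol, selected with oligo(dT) and made into libraries with TruSeq RNA v2. Per the submitters' processing notes FastQC, Bowtie and DESeq2 were used with the genome build hg38, with no versions or roles. The counter, the annotation and any batch handling are not given in the sources used here, nor are doses and times except for 3 libraries labelled 24 h, 1x and 100x. Counts were not analysed here, so the depth is unknown and no counting intervals are given. Columns labelled IRF3 without the letters KO were read as the IRF3 knockout, as their titles give it. Nothing in the labels says whether replicates are separate cultures, so the p values measure the spread between these samples, which may be technical.

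The table was checked as follows. No pair of columns was identical, and 1103 genes were at 0 in every library. The 10 most abundant genes took 7.18 to 13.99% of the total per library, and no mitochondrially encoded gene is listed. Gene positions are from GENCODE v29 on GRCh38.

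Choices below were made before the data were examined, unless stated. The 14131 genes with a TPM of at least 1 in at least 2 libraries were tested on log2(TPM + 1). A single limma model (version 3.58.1, R 4.3.3) with a mean for each of 87 groups was fitted over all libraries, with eBayes and a mean-variance trend, leaving 30 residual degrees of freedom (4.17 prior). A gene was called with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested and a change of at least 1 in size. A group with 1 library in a comparison is assumed to vary like the replicated groups. Differences between responses were tested as interaction contrasts of the same model. Gene lists were written down beforehand and tested with limma's fry, which asks whether a list moves one way on balance and does not compare it with other genes. Its p values were adjusted over 360 tests of lists and comparisons, and over 52 comparisons for the level of the interferon-stimulated list. Counts adjusted over the list alone use the p values of the list's members only. The target of a knockout was left out of every list in its comparison. In the single-library conditions, list medians were set against 10000 random lists matched on expression over 20 bins.

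Genes named follow a rule: the 8 targets, IFNB1, IFNL1, CXCL10, CCL5, ISG15, IFIT1, MX1, TNF, IL6 and IL1B, the 10 largest rises and 10 largest falls per WT comparison (5 and 5 for other comparisons) among genes past the test with a mean of at least 5 TPM in 1 group and no overlap between libraries, and up to 4 members per list with the largest change among those called, or 2 where none was called. Exceptions are said where they occur.

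Alternatives were a pseudocount of 0.5, no filter, median-of-ratios scaling (factors 0.702 to 1.2109) and a replicate block. Others were a model of the compared groups only and leaving out each replicate in turn. Untreated WT monocyte replicate 4 is the only library with number 4, so the block fits it exactly and takes it out of every comparison. A model of the compared groups only with a block as well has few residual degrees of freedom, so a low count there can come from that alone. In the comparisons of the interferon-stimulated list that do not hold the left-out library, the p values of the full set stay in the adjustment. The method was tested on simulated data with 100 genes shifted by 1 and 100 by 2: at a shift of 2 it recovered 90% for IFNB1 protein, 95% for cGAMP and 82% for the difference between the IRF3 knockout and WT, and at a shift of 1 it recovered 45, 37 and 24 of 100 past both thresholds (56, 50 and 25 by the adjusted p alone). Unchanged genes called were 2, 2 and 9. A list left unshifted had unadjusted fry p values of 0.308, 0.0459 and 0.333. The simulated noise was independent between libraries, so it lacks deviations shared by same-numbered libraries, and false calls in the real data may be more frequent.

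Whether replicate numbers pair the libraries was tested by correlating the deviations of same-numbered libraries from their group means. With 3 pairs the correlations were 0.557 to 0.728 for cGAMP in WT, 0.534 to 0.741 for cGAMP in the IRF3 knockout, 0.484 to 0.658 for IRF3 knockout against WT and 0.33 to 0.661 for IRF9 knockout against WT, so the numbers pair these libraries. For digitonin against untreated they were -0.298 to 0.434, and the numbers do not pair these. The other comparisons hold 2 pairs. The nearest library of each WT library was found over 13875 genes outside the fixed lists, a check chosen after the data were seen.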

Results

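RNA sequencing was applied to 117 libraries of THP1, a human monocytic leukaemia line, of which 93 were grown as monocytes and 24 were differentiated into macrophages with PMA, a phorbol ester. Besides wild-type (WT) cells the libraries come from 9 knockout genotypes: IRF1, IRF2, IRF3, IRF5, IRF7, IRF8, IRF9 (interferon regulatory factors) and IFNAR2 (a subunit of the type I interferon receptor) singly, and IRF3 with IRF7. Further libraries come from IRF3 knockout and double knockout cells that overexpress IRF3, IRF7 or GFP. Monocytes were untreated or received IFNB1 protein (interferon beta), digitonin (a detergent that permeabilises the plasma membrane), digitonin with cGAMP (the second messenger made by the DNA sensor cGAS, which activates STING) or LPS (bacterial lipopolysaccharide, the ligand of TLR4), and macrophages were untreated or received LPS. By state, genotype and treatment the libraries form 87 groups, and 65 of these hold 1 library. WT monocytes have 4 untreated, 3 digitonin, 3 cGAMP, 2 IFNB1 and 2 LPS libraries, and WT macrophages have 2 untreated and 2 LPS libraries. Values are TPM (transcript abundance scaled to a fixed total per library), as deposited by the authors, for 19207 gene symbols, so the read depth is unknown. Between 11484 and 12179 genes reached 1 TPM per library. Below, ± is the SD between the libraries of a group, changes are on the log2(TPM + 1) scale, SE is the standard error of a change, and adjusted p values come from limma. "Higher" or "lower" as a count means an adjusted p under 0.05 and a change of at least 1.

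The first question for each knockout is what happened to the transcript of its target. IRF3 mRNA was at 38.0 ± 12.7 TPM (n = 3) in untreated IRF3 knockout monocytes against 76.4 ± 15.7 TPM (n = 4) in WT, a fall of -1.02 (adjusted p = 0.00803, limma). In the double knockout (n = 2) IRF3 fell by 1.06 (adjusted p = 0.0197) and IRF7 fell by 2.15 (adjusted p = 0.0196, limma), to 5.83 ± 6.64 TPM from 22.97 ± 11.35 TPM. IRF8 mRNA rose in the IRF8 knockout, to 1340 ± 49.2 TPM (n = 2) from 488 ± 49.4 TPM (change 1.46, adjusted p = 3.52e-06, limma). The other targets were not called: IRF1 (38.7 against 32.2 TPM), IRF2 (44.4 against 22.1), IRF5 (56.7 against 74.1), IRF7 in its single knockout (20.5 against 23.0), IRF9 (42.9 against 49.9) and IFNAR2 (46.7 against 69.1). The calls of IRF3 lie at the size threshold and ended without WT replicate 4 or knockout replicate 1 in both genotypes, and in the single knockout also without knockout replicate 3 (changes from -1.27 to -0.85), and with a replicate block that change was -0.89, short of the size threshold, while the block ended the call in the double knockout as well. IRF7 in the double knockout was at -0.93 without knockout replicate 1 and was not called without WT replicate 2. Transcript levels do not test an edit that leaves the transcript in place, and the edits themselves were not analysed here. On GRCh38 the targets lie on chromosome 5 from 132481609 to 132490798 (IRF1), 4 from 184387713 to 184474580 (IRF2), 19 from 49659569 to 49665875 (IRF3), 7 from 128937612 to 128950035 (IRF5), 11 from 612553 to 615999 (IRF7), 16 from 85898803 to 85922609 (IRF8), 14 from 24161053 to 24166565 (IRF9) and 21 from 33229901 to 33265675 (IFNAR2).

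IFNB1 protein in WT monocytes shows the response to type I interferon itself. IFIT2, which acts against viral RNA, reached 1419 ± 594 TPM (n = 2) from 14.04 ± 9.41 TPM (n = 4), a change of 7.07 (SE 0.81, adjusted p = 1.06e-07, limma), and MX1, a dynamin-like antiviral GTPase, reached 799 ± 245 TPM from 42.3 ± 30.1 TPM. Of 46 interferon-stimulated genes tested, 41 rose (43 adjusted over the list alone), with a median change of 2.94 (adjusted p = 3.57e-07). Of 20 guanylate-binding protein and CXCR3 chemokine genes 15 rose (15 adjusted over the list alone, median 2.29, adjusted p = 3.2e-13), among them CXCL10 (6.25), CXCL9 (5.79) and GBP1 (5.10). In the MHC class I list 3 of 17 rose (adjusted p = 0.0154), including the peptide transporter TAP1, and in the innate sensing list 4 of 17 rose (adjusted p = 0.00646), including the DNA sensor IFI16. Several factors of the pathway rose as well: IRF1 to 313 ± 146 TPM (3.23), IRF7 to 141 ± 57.4 TPM (2.63) and IRF9 to 157 ± 9.28 TPM (1.78). IFNB1 mRNA was at 0.137 TPM with the protein and 0.139 TPM without it. In all 314 genes were higher and 18 lower, the lower ones including CALHM2 (-1.53). The calls of IRF7 and IRF9 ended when treated replicate 2 was left out (highest adjusted p over all alternatives 0.204 and 0.32), and that of IRF9 also without treated replicate 1 and with a replicate block. A model of the compared groups only called 102 genes and ended the calls of IFIT2 (adjusted p = 0.0897), MX1 (0.333), CALHM2 (0.123), IRF7 and IRF9, and with a block as well it called 0 genes by limma (1581 at an unadjusted p under 0.05 in the reported model), so that those of CXCL10, CXCL9, GBP1 and IRF1 ended too (adjusted p from 0.125 to 0.137). With that block, untreated replicates 3 and 4 have no treated partner and are fitted exactly. Few residual degrees of freedom remain, so a low count can come from that alone. Untreated WT replicate 4 and 3 other WT libraries have an IRF2 knockout library as their nearest relative over genes outside the fixed lists. Without these 4 the MHC class I list was not called (adjusted p = 0.0721).

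Digitonin alone is the control for cGAMP delivery, and it had a response of its own in WT monocytes. Immediate early genes responded strongly: 14 of 18 rose and 1 fell (17 and 1 adjusted over the list alone), with a median change of 3.52 (adjusted p = 1.62e-08). FOSB, a transcription factor of the AP-1 family, went from 26.0 ± 24.4 TPM (n = 4) to 435 ± 74.8 TPM (n = 3), and EGR2 rose by 4.28 (SE 0.43). Of 31 NF-kB inflammatory genes 16 rose (18 adjusted over the list alone, median 1.25, adjusted p = 2.57e-05), led by the chemokines CCL4 (5.32) and CCL3 (4.26) and by IL1B (3.66). Of 17 stress response genes 7 rose (7 adjusted over the list alone, adjusted p = 1.92e-06), including PPP1R15A (3.18) and DDIT3 (2.38), which act in the integrated stress response. Of 20 cholesterol synthesis genes 8 rose (8 adjusted over the list alone), among them HMGCS1 (1.82), with an adjusted p for the list of 0.0535, and 0.0483 with scaling. MYC fell by 1.83 and the receptor gene P2RY8 fell by 2.18. The cell cycle list passed as a whole (median -0.59, adjusted p = 0.0498) although no member was called by itself, and its p was 0.0501 with a pseudocount of 0.5. IFNB1 mRNA (0.406 TPM) and MX1 (21.4 ± 12.7 TPM) were not called, and MX1 was called lower (-1.52) without the 4 set-apart libraries. In all 525 genes were higher and 133 lower. A model of the compared groups only called 393 genes, and 156 with a replicate block as well, where EGR2 was not called (adjusted p = 0.0535).

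cGAMP added to digitonin asks what STING activation does beyond permeabilisation. IFNB1 mRNA went from 0.406 ± 0.44 TPM to 1823 ± 930 TPM (n = 3 each), a change of 10.27 (SE 0.40, adjusted p = 3.28e-21, limma), and IFNL1, a type III interferon, from 0.075 ± 0.13 to 551 ± 374 TPM (8.66, adjusted p = 1.87e-19). IFNB1 lies on chromosome 9 from 21077105 to 21077963 and IFNL1 on chromosome 19 from 39296325 to 39298673. Of 13 type I and III interferon genes 6 rose (6 adjusted over the list alone, adjusted p = 1.41e-12). Interferon alpha genes stayed low: IFNA14 reached 5.66 ± 4.52 TPM and was listed at 0 in the digitonin libraries, and reads can be shared among these near-identical paralogs. Of 46 interferon-stimulated genes 36 rose (37 adjusted over the list alone, median 2.87, adjusted p = 7.17e-08), with IFIT2 at 14221 ± 2496 TPM (9.81), IFIT1 at 2885 ± 662 TPM (8.41) and HERC5, a ligase for ISG15, at 1302 ± 315 TPM (8.18). MX1 reached 111 ± 56.9 TPM (2.36, adjusted p = 0.0462), a call that ended under 6 of 13 alternatives (changes from 1.79 to 2.89), among them leaving out cGAMP replicate 1 or 2 or digitonin replicate 2 or 3. Of 20 guanylate-binding protein and CXCR3 chemokine genes 13 rose (13 adjusted over the list alone, median 1.93, adjusted p = 1.88e-12).

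Genes also fell with cGAMP. The transcription factor gene HES1 fell by 4.07, the thrombin receptor gene THBD fell by 4.06, the kinase gene SGK1 fell by 3.75 and the phosphatase gene DUSP7 fell by 3.48. Of 20 cholesterol synthesis genes 7 fell (7 adjusted over the list alone, median -0.84, adjusted p = 0.00112), among them HMGCS1 (-2.05) and SQLE (-2.02), both enzymes of the pathway. Stress response genes moved both ways: 2 rose and 6 fell of 17 (2 and 6 adjusted over the list alone, median -0.65, adjusted p = 0.00326), with PPP1R15A at 2.42 and HMOX1 at -3.33. IL1B fell by 1.54 (adjusted p = 0.017, not called with scaling, without digitonin replicate 2 or cGAMP replicate 3 or in a model of the compared groups only), and TNF was at 177 ± 104 against 117 ± 7.51 TPM (adjusted p = 0.834). In all 560 genes were higher and 862 lower, and the median of all genes moved by -0.13. With median-of-ratios scaling that median became 0.04 and the split 673 higher and 525 lower. The stress list was not called with scaling (adjusted p = 0.0874), and the MHC class I list (median 0.27, adjusted p = 0.0703) was called with scaling (adjusted p = 0.000919) and with a replicate block (adjusted p = 0.0126).

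The IRF3 knockout asks which part of the cGAMP response needs IRF3. IFNB1 mRNA reached 3.03 ± 1.07 TPM (n = 3) there against 1823 TPM in WT, IFNL1 was listed at 0 in all 3 libraries with cGAMP and all 3 without, and IFIT1 was at 1.23 ± 1.05 TPM against 2885 TPM. The difference between the 2 responses was called for 27 of 46 interferon-stimulated genes (35 adjusted over the list alone, median -2.79, adjusted p = 0.000115), 6 of 13 interferon genes (6 adjusted over the list alone, adjusted p = 9.72e-09) and 10 of 20 guanylate-binding protein and CXCR3 chemokine genes (12 lower and 1 higher adjusted over the list alone, adjusted p = 3.26e-08), all of these toward a smaller response. For IFNB1 it was -8.42 (SE 0.56, adjusted p = 6.98e-14, limma) and for HERC5 -8.06. In the other direction the response of RGS1, a regulator of G protein signalling, differed by 6.41, that of SGK1 by 5.59 and that of the chemokine receptor gene CCR1 by 4.35. In all 314 genes had a higher and 471 a lower response than in WT, and with scaling 225 and 548. The stress response list (median 0.58, adjusted p = 0.0277) was not called with scaling (adjusted p = 0.106).

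Within the IRF3 knockout cGAMP raised 21 genes and lowered 2 (PTRF -1.22, GCNT1 -1.20). Of the 31 NF-kB genes 4 rose (4 adjusted over the list alone): CCL4 reached 445 ± 295 TPM from 44.4 ± 8.02 TPM (adjusted p = 0.0113) and TNF reached 852 ± 320 TPM from 104 ± 14.5 TPM (adjusted p = 0.0429, limma, n = 3 each). OASL, an OAS-like antiviral gene, rose by 3.396 (adjusted p = 0.00135) and IFNB1 by 1.84 (adjusted p = 0.0265). The TNF call ended under 10 of 11 alternatives (changes from 2.68 to 3.17, highest adjusted p 0.341), staying only without the set-apart libraries, those of IFNB1, PTRF and GCNT1 under 6, 7 and 7 of 11, and that of CCL4 without digitonin replicate 2 or 3 or cGAMP replicate 1. The TNF response was not called as different from that of WT (2.57, adjusted p = 0.113). That of IL1B was (2.12, adjusted p = 0.0479), and ended under 13 of 17 alternatives. The total of 23 genes lay between 7 and 21 when single libraries were left out, lowest without cGAMP replicate 1, and was 15, 9 and 9 without digitonin replicates 1, 2 and 3. Without the 4 set-apart WT libraries, which enter here only through the pooled spread, it was 35.

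IRF9 acts downstream of the type I interferon receptor, so its knockout asks how much of the cGAMP response runs without it. The response was large there: IFNB1 reached 972 ± 192 TPM (n = 2), IFIT2 12741 ± 547 TPM and IFIT1 2877 ± 135 TPM, from 0.355, 12.3 and 2.12 TPM with digitonin. Of 46 interferon-stimulated genes 30 rose (31 adjusted over the list alone, median 2.99, adjusted p = 1.92e-06), and 11 of 20 guanylate-binding protein and CXCR3 chemokine genes rose (11 adjusted over the list alone, adjusted p = 1.05e-08). MX1 was at 7.50 ± 1.56 TPM against 2.57 ± 0.62 TPM (adjusted p = 0.622). Against WT the response of the interferon-stimulated list had a median difference of 0.16 (adjusted p = 1). The level of that list with cGAMP was below WT by its median (-0.73), with 18 of 46 genes lower by at least 1 and 0 higher. The level did not pass by fry (adjusted p = 0.129), and passed under 1 of 10 alternatives, the one without the set-apart libraries. The interferon genes differed (median -0.74, adjusted p = 0.000815), with 2 of 13 called (3 adjusted over the list alone), among them IFNA14, at 0.169 TPM with cGAMP in the knockout, a call that ended without knockout digitonin replicate 1 or cGAMP replicate 2. Over all genes the difference was called for 6, and for 1 to 18 when single libraries were left out, the extremes being without knockout digitonin replicate 1 and without WT cGAMP replicate 3, with 10 without knockout cGAMP replicate 2, and it was called for 16 without the set-apart libraries. Within the knockout 503 genes were higher and 640 lower, and 606 and 407 with scaling, which moved the median of all genes from -0.12 to 0.04. As in WT, HES1 and THBD fell, and 8 of 20 cholesterol synthesis genes fell (8 adjusted over the list alone, adjusted p = 0.00692, and 0.0746 with scaling). The stress list passed too (median -0.69, adjusted p = 0.0277, and 0.267 with scaling).

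**Figure D1:**
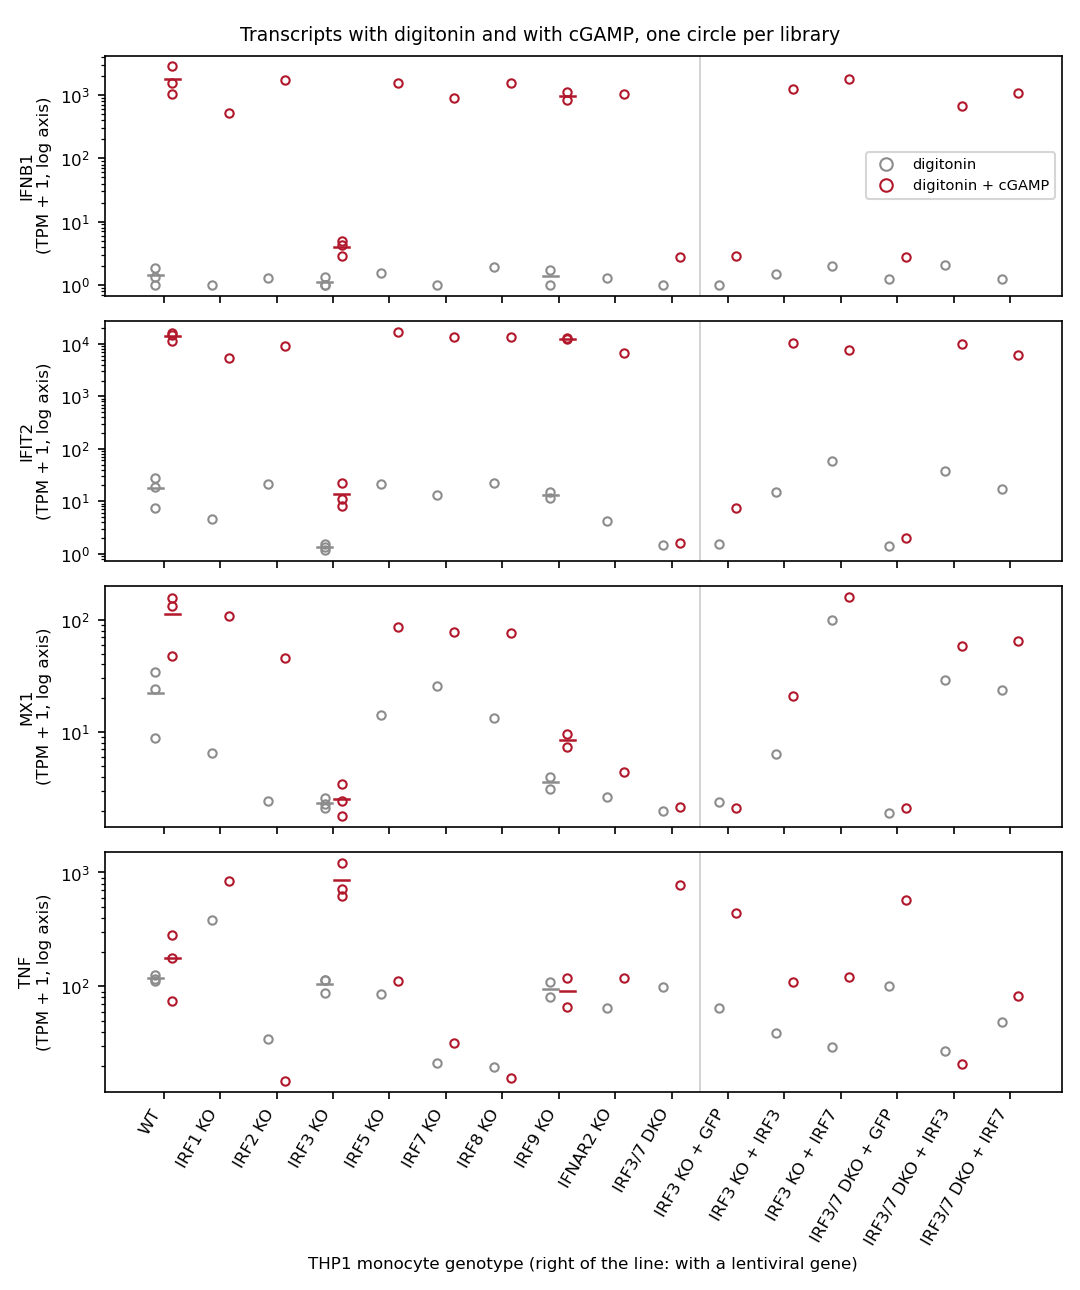
TPM + 1 of IFNB1, IFIT2, MX1 and TNF on a log axis for monocytes with digitonin and with digitonin and cGAMP, one circle per library and a bar at the mean of replicated groups. Genotypes right of the vertical line overexpress GFP, IRF3 or IRF7. IFNB1 with cGAMP averaged 1823 TPM in WT and 3.03 TPM in the IRF3 knockout.

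Single libraries carry the other genotypes with cGAMP, and the values of their genes were not tested here, while the level of their interferon-stimulated list is tested below. IFNB1 mRNA was at 523 TPM in the IRF1 knockout, 914 in the IRF7 knockout, 1060 in the IFNAR2 knockout, 1541 in the IRF8 knockout, 1543 in the IRF5 knockout and 1756 in the IRF2 knockout. In the IFNAR2 knockout, which targets the receptor for secreted interferon, IFIT2 (named after its value was seen) was at 6695 TPM and MX1 at 3.38 TPM. The median change of the interferon-stimulated list ranged from 1.87 in the IFNAR2 knockout to 3.99 in the IRF2 knockout, and in the IRF3/IRF7 double knockout it was 0.07, with IFNB1 at 1.79 TPM.

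Overexpression in the IRF3 knockout and in the double knockout asks which factor restores the response, again with 1 library per condition. With GFP, IFNB1 with cGAMP was at 1.84 and 1.77 TPM. With IRF3 (its mRNA at 1174 and 1178 TPM) IFNB1 was at 1256 and 684 TPM and IFNL1 at 45.3 and 38.4 TPM. The 8 interferon alpha genes past the filter, of 13 annotated, together gave 1.34 and 0.38 TPM there. This sum was formed after their values were seen. With IRF7 (its mRNA at 479 and 517 TPM) IFNB1 was at 1779 and 1091 TPM, IFNL1 at 3.12 and 1.83 TPM, and the interferon alpha genes summed to 532 and 326 TPM, of which IFNA14 made up 316 and 161 TPM. The same sum was 7.89 TPM in WT, 13.3 TPM in the IRF5 knockout, 4.78 TPM in the IRF8 knockout, 3.07 TPM in the IRF2 knockout, 0.17 TPM in the IRF9 knockout and 0 in the IRF1, IRF3, IRF7, IFNAR2 and double knockouts. Relative to digitonin, 12 and 11 of 13 interferon genes were higher by at least 1 with IRF7 and 3 and 2 with IRF3. These 13 are the genes past the filter, of 20 in the table. With cGAMP, IFNA4, IFNA5, IFNA16, IFNA17 and IFNA21 reached a group mean of 1 TPM only with IRF7. The IRF7 libraries thus helped to choose the genes counted, which favours a high count there. The interferon-stimulated list had median changes of 2.22 and 1.61 with IRF3, 0.99 and 1.26 with IRF7 and 0.03 and 0.08 with GFP, while MX1 in the digitonin libraries was already at 98.0 and 22.8 TPM with IRF7 and at 5.35 and 28.1 TPM with IRF3. The interferon alpha genes form a cluster on chromosome 9 from 21165637 to 21441316, and reads shared among them leave the split between members uncertain.

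The response to IFNB1 protein was compared between WT and the knockouts of IRF3 and IRF9, which sit upstream of interferon production and downstream of its receptor. In the IRF3 knockout (n = 2 treated, 3 untreated) 40 of 46 interferon-stimulated genes rose (43 adjusted over the list alone, median 3.29, adjusted p = 3.07e-07), with MX1 at 272 ± 49.5 TPM from 3.03 ± 0.87 TPM. IFIT1 was at 160 ± 15.3 TPM and listed at 0 without the protein. Of 20 guanylate-binding protein and CXCR3 chemokine genes 11 rose (14 adjusted over the list alone, adjusted p = 1.05e-08). In all 173 genes were higher and 0 lower by limma, with 641 genes at an unadjusted p under 0.05, and 106 were higher without treated replicate 2. The responses of CD274, which encodes PD-L1 (-2.32, adjusted p = 0.00275), and CXCL9 (adjusted p = 0.0369) were smaller than in WT, and these were the 2 genes called, against 24 without WT treated replicate 2 and 0 by limma without treated knockout replicate 1 (185 at an unadjusted p under 0.05 in the reported model). The call of CD274 ended with a pseudocount of 0.5 and without treated knockout replicate 1, and that of CXCL9 under 13 of 16 alternatives. CXCL9 was at 6.41 ± 2.14 TPM with the protein in the knockout and 63.3 ± 36.3 TPM in WT, and listed at 0 in the untreated knockout libraries. The guanylate-binding protein and chemokine list differed as a whole (median -0.67, adjusted p = 0.0187), and not with scaling (adjusted p = 0.0641).

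In the IRF9 knockout (n = 2 treated, 3 untreated) IFIT1 was at 2.76 ± 0.17 TPM with IFNB1 protein and 2.67 ± 0.81 TPM without, and MX1 at 3.76 ± 0.51 and 2.10 ± 0.07 TPM. The response differed from WT for 11 of 46 interferon-stimulated genes (34 adjusted over the list alone, median -2.22, adjusted p = 0.00757), with IFIT1 at -6.02 (adjusted p = 0.00974, up to 0.0916 without WT treated replicate 2 or either treated knockout replicate) and CXCL10 at -5.20 (adjusted p = 1.64e-05). A set of genes still rose there: IRF1 reached 231 ± 77.3 TPM from 24.0 ± 7.17 TPM, a change of 3.22 (adjusted p = 6.29e-07, limma), with a difference from the WT response of -0.01. The kinase gene PIM1 rose by 3.59 and the oncostatin M receptor gene OSMR rose by 3.51. Of 20 guanylate-binding protein and CXCR3 chemokine genes 5 rose (9 adjusted over the list alone, median 0.98, adjusted p = 6.56e-05), a smaller response than in WT (median difference -0.95, adjusted p = 2.57e-05). In all 100 genes were higher and 6 lower, and the total of 106 was 51 without treated replicate 1 and 70 without treated replicate 2. Of the 100, 84 were also called higher in WT. In the IFNAR2 knockout library with IFNB1 protein, IRF1 was at 39.5 TPM, IFIT1 at 32.0 TPM and MX1 at 15.5 TPM, against means of 28.2, 0.947 and 1.90 TPM in the untreated libraries.

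**Figure D2:**
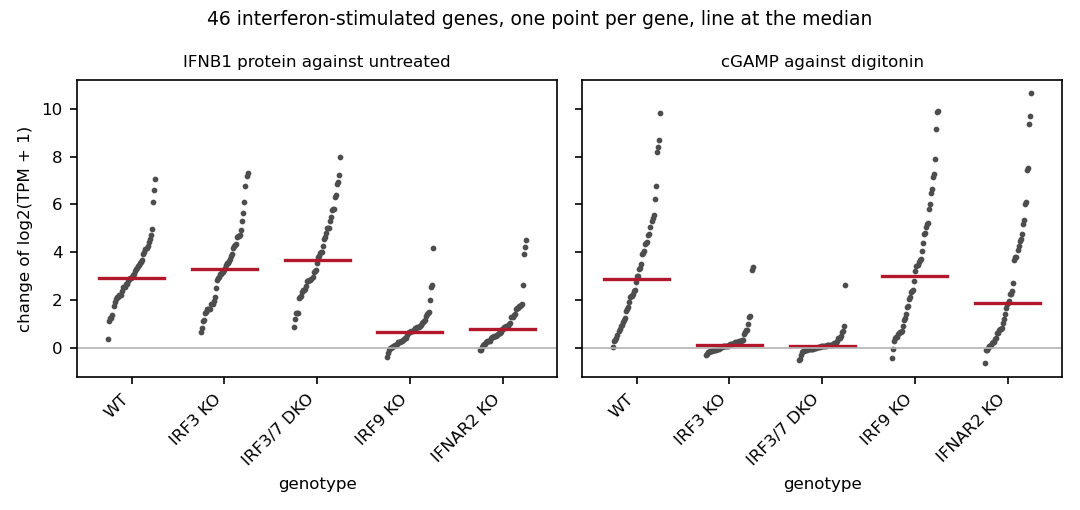
Change of each of 46 interferon-stimulated genes with cGAMP and with IFNB1 protein in WT, in the IRF3, IRF9 and IFNAR2 knockouts and in the IRF3/IRF7 double knockout, on the log2(TPM + 1) scale, one point per gene and a line at the median. The list medians are 2.87 (cGAMP) and 2.94 (IFNB1) in WT, 2.99 and 0.66 in the IRF9 knockout and 0.13 and 3.29 in the IRF3 knockout.

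The level of the interferon-stimulated list was also compared between each knockout and WT under the same condition, 52 comparisons in all, 8 of which passed. That number was 17 with a replicate block, 16 of the 27 then tested without the set-apart libraries, 14 without untreated WT replicate 4, 6 without any 1 untreated IRF3 knockout replicate, and 5 without untreated WT replicate 1, 2 or 3 or either untreated IRF2 knockout replicate. With IFNB1 protein the list was lower in the IRF9 (-3.39, adjusted p = 1.64e-06) and IFNAR2 knockouts (-3.34, adjusted p = 4.85e-05). With cGAMP it was lower in the IRF3 knockout (-4.19, adjusted p = 3.02e-10), the double knockout (-4.25, adjusted p = 2.22e-07) and the IFNAR2 knockout (-1.40, adjusted p = 0.0445, not called without WT cGAMP replicate 1 or 2, and through the adjustment alone not without untreated WT replicate 1, 2 or 3 or any untreated IRF2 or IRF3 knockout replicate). With LPS in macrophages it was lower in the IRF3 knockout (-1.66, adjusted p = 0.0209). The IRF8 (-1.48) and double knockouts (-1.17) were lower with LPS in macrophages too, but did not pass. Both passed with a replicate block, and IRF8 also with scaling. In untreated monocytes the list was lower in the IRF2 (-1.45, adjusted p = 0.0429) and IRF3 knockouts (-0.90, adjusted p = 0.0429). Both of the last calls ended when any of WT replicates 1, 2 and 3 or any knockout replicate was left out, and that of IRF2 also with scaling. Against WT replicate 4 alone, a comparison chosen after the data were seen, the list of the IRF2 knockout was at 0.0517. That library was picked as the nearest to the IRF2 knockout, which favours a small difference, so this value cannot decide whether the list fell. The IRF9 knockout lay just outside (-0.87, adjusted p = 0.0523), and was called with a replicate block (-1.24, adjusted p = 0.00113), which also takes out WT replicate 4. Without WT replicate 4 the untreated IRF1 (-1.48), IRF9 (-1.24), IFNAR2 (-1.28) and double knockouts (-1.11) passed as well. Knockout arms with 1 library are assumed here to vary like the replicated groups.

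**Figure D3:**
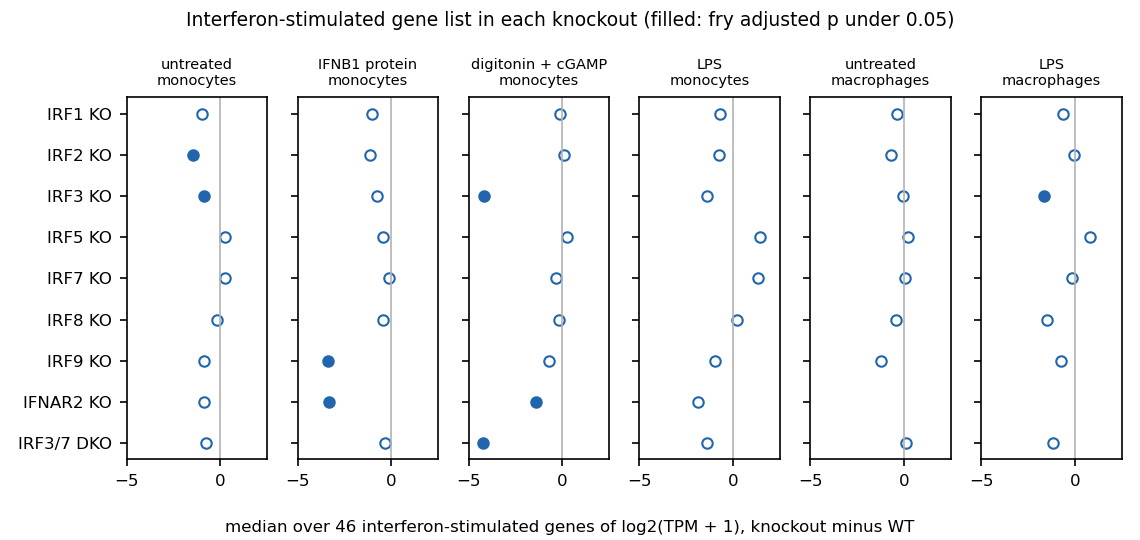
Median level of the interferon-stimulated list in each knockout minus WT under the same condition, on the log2(TPM + 1) scale, filled where the limma fry test passed over the 52 comparisons. The lowest value is -4.25, in the double knockout with cGAMP.

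LPS asks about TLR4 signalling in the 2 states. In WT monocytes IL1B reached 7267 ± 3100 TPM (n = 2) from 6.28 ± 1.43 TPM (n = 4), a change of 9.92 (SE 0.50, adjusted p = 8.65e-17, limma), and TNF 2551 ± 1479 TPM from 68.7 ± 22.3 TPM. All 31 NF-kB inflammatory genes rose (31 adjusted over the list alone, median 5.62, adjusted p = 1.51e-17), including CCL4 (9.88) and the neutrophil chemokines IL8 (7.96) and CXCL2 (7.65). IFNB1 mRNA rose slightly, to 3.34 ± 2.48 TPM (adjusted p = 0.00208, not called without LPS replicate 1), while IFIT1 was at 25.4 ± 34.6 against 15.1 ± 10.4 TPM (adjusted p = 0.924, with a change of -2.55 without LPS replicate 1 and 2.19 without LPS replicate 2) and the interferon-stimulated list did not pass (median -0.36, adjusted p = 0.988). The chemokine receptor genes CCR2, CCR1 and CX3CR1 fell, by -3.77, -2.72 and -2.49. Of 24 cell cycle genes 7 fell (7 adjusted over the list alone, adjusted p = 0.0299, 0.267 with scaling and 0.085 with a replicate block), with PLK1 at -1.80 and MKI67 at -1.32. Immediate early genes (9 of 18 rose and 1 fell, 10 and 1 adjusted over the list alone, adjusted p = 4.54e-05), guanylate-binding protein and CXCR3 chemokine genes (5 of 20, adjusted p = 0.0238, and 0.085 with a replicate block) and stress response genes (2 of 17, 3 adjusted over the list alone, adjusted p = 0.0385) also passed. In all 436 genes were higher and 811 lower, with a median of all genes of -0.25. With scaling that median was 0 and the split 568 and 258. One of the set-apart WT libraries is LPS replicate 2: without it alone the counts were 602 and 1520, without the 4 set-apart libraries they were 621 and 1756, and the stress list was not called (adjusted p = 0.14). A model of the compared groups only called 178 genes and ended the calls of CCR2 (adjusted p = 0.0522), CX3CR1 (0.102) and IFNB1 (0.08), and with a replicate block as well it called 0 genes by limma (4713 at an unadjusted p under 0.05 in the reported model).

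In WT macrophages LPS raised the same NF-kB list in full, 31 of 31 (31 adjusted over the list alone, median 4.98, adjusted p = 1.84e-14), with CXCL1 at 8.54 and TNF at 1394 ± 785 TPM from 13.3 ± 14.6 TPM (n = 2 each). Here IFNB1 mRNA reached 103 ± 105 TPM from 0.146 ± 0.206 TPM (5.99, adjusted p = 2.22e-11, limma), with 176.9 TPM in replicate 1 and 28.5 TPM in replicate 2. IFIT2 reached 882 ± 997 TPM (6.83) and OASL 138 ± 110 TPM (5.44), and 10 of 46 interferon-stimulated genes rose (11 adjusted over the list alone), although the list as a whole did not pass (median 0.72, adjusted p = 0.137) except without the set-apart libraries (median 1.01, adjusted p = 0.000565). Of 20 guanylate-binding protein and CXCR3 chemokine genes 8 rose (11 adjusted over the list alone, adjusted p = 4.32e-07), and of 18 immediate early genes 6 rose (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.00703). IRF8 rose by 1.71 and the proton-sensing receptor gene GPR65 fell by 3.04. In all 363 genes were higher and 339 lower (439 and 138 with scaling, which moved the median of all genes from -0.23 to 0.01), and the total of 702 was 440 without LPS replicate 1 and 1340 without LPS replicate 2. A model of the compared groups only called 0 genes by limma (2701 at an unadjusted p under 0.05 in the reported model), ending every call above by gene, with adjusted p values of 0.403 for IFNB1, 0.433 for IFIT2, 0.375 for TNF, 0.539 for IRF8, 0.393 for GPR65 and 0.124 for CXCL1, and with a replicate block as well it called 6 genes, CXCL1 among them. The 2 states differed in their response for IFNB1 (4.18, adjusted p = 9.37e-05), IFIT2 (6.39, adjusted p = 0.00232) and OASL (4.62), all larger in macrophages. Those of IFIT2 and OASL ended without monocyte LPS replicate 2 or macrophage LPS replicate 1 (adjusted p up to 0.0713 and 0.0653). IL1B had a smaller response there (-6.31, adjusted p = 2.1e-06), from a macrophage level of 525 ± 172 TPM before LPS. The guanylate-binding protein and chemokine list differed as a whole (median 0.93, adjusted p = 0.014; 2 of 20 genes, 5 adjusted over the list alone). The difference was called for 55 genes as higher and 54 as lower, for 123 and 171 without the set-apart libraries, for 63 and 145 without monocyte LPS replicate 2 and for 143 and 100 without macrophage LPS replicate 2.

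**Figure D4:**
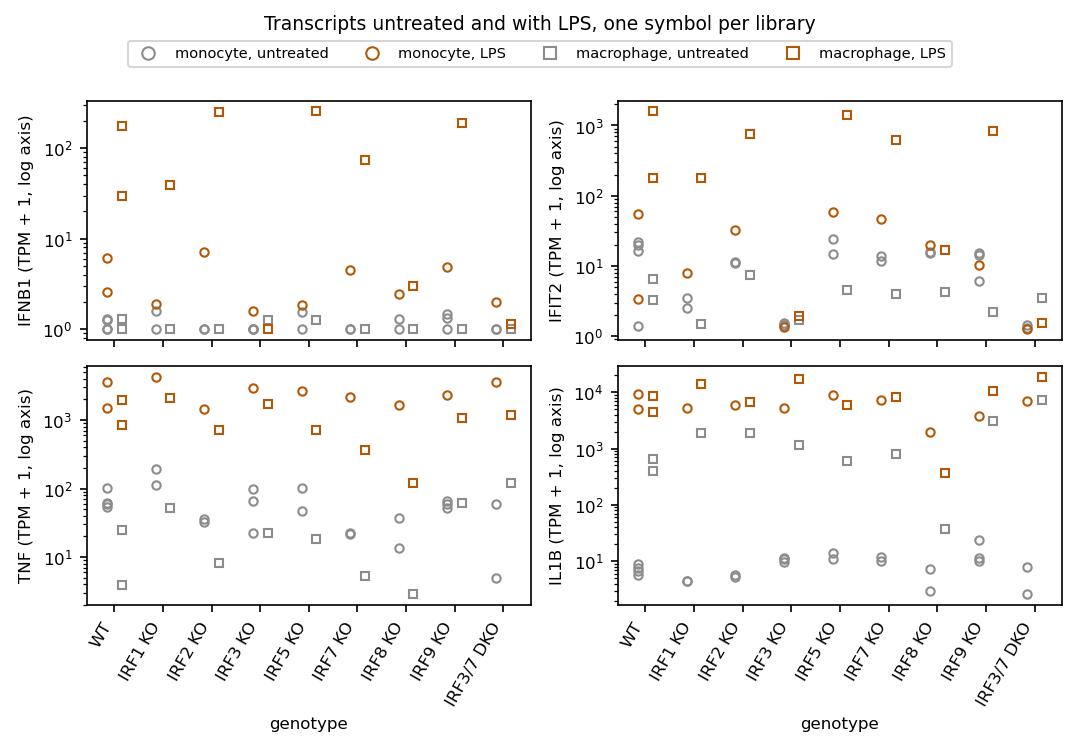
TPM + 1 of IFNB1, IFIT2, TNF and IL1B on a log axis for untreated and LPS-treated monocytes (circles) and macrophages (squares) of WT and 8 knockout genotypes, one symbol per library. In WT, IFNB1 with LPS averaged 3.34 TPM in monocytes and 103 TPM in macrophages.

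Knockout macrophages with LPS were single libraries and have no test by gene. IFNB1 was listed at 0 in the IRF3 knockout and was at 0.126 TPM in the double knockout, 113 TPM in the double knockout with IRF3 and 11.6 TPM with IRF7. TNF in the same 4 libraries was at 1725, 1170, 690 and 930 TPM. Elsewhere IFNB1 was at 38.5 TPM in the IRF1 knockout, 73.7 in the IRF7 knockout, 191 in the IRF9 knockout, 250.0 in the IRF2 knockout and 255 in the IRF5 knockout. In IRF8 knockout macrophages IFNB1 was at 1.97 TPM, TNF at 118 TPM and IL1B at 369 TPM after LPS. Their untreated library already had TNF at 1.87 TPM and IL1B at 36.35 TPM, against WT means of 13.3 and 525 TPM, and SPP1, a macrophage marker chosen after its value was seen, at 868 TPM. The SD of TNF in untreated WT macrophages, given above, is larger than its mean, so the TNF contrast is uncertain. The LPS receptor genes CD14 and LY96, chosen after their values were seen, were at 3.05 and 2.80 TPM in the untreated library and 1.97 and 2.73 TPM in the one with LPS, where 28 of 31 NF-kB genes were higher by at least 1 (median 3.43).

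PMA differentiation asks how the resting cells differ between states. In untreated WT macrophages (n = 2) against monocytes (n = 4) 1491 genes were higher and 1238 lower. A model of the compared groups only called 1844 genes, and with a replicate block as well it called 0 by limma (6024 at an unadjusted p under 0.05 in the reported model). Of 23 macrophage differentiation markers 19 rose (20 adjusted over the list alone, median 2.76, adjusted p = 8.46e-11): the gelatinase gene MMP9 reached 572 ± 293 TPM from 0.317 ± 0.238 TPM (8.68, adjusted p = 3.18e-21, limma), the scavenger receptor gene MSR1 601 ± 587 TPM (7.52) and the lipid carrier gene FABP4 280 ± 329 TPM (7.01). SPP1, osteopontin, was at 10766 ± 12494 TPM. Of 24 cell cycle genes 21 fell (22 adjusted over the list alone, median -1.45, adjusted p = 1.1e-06), with TOP2A and CCNA2 at -2.20 each, and 11 of 20 cholesterol synthesis genes fell (11 adjusted over the list alone, adjusted p = 0.000261). MS4A3 fell by -5.73, CTSG fell by -4.67 and IRF8 fell by -2.98, to 62.7 ± 22.5 TPM. IL1B rose by 6.16 while TNF fell by 2.78, not called without macrophage replicate 2 or without the set-apart libraries. The sensing list passed (3 of 17 rose and 2 fell, adjusted p = 0.0288, and 0.251 with a replicate block), with LY96 at 3.29 and MB21D1, the cGAS gene, at -2.05. The NF-kB list (13 of 31 rose and 2 fell, adjusted p = 0.025, and 0.106 with a replicate block) and the MHC class I list (4 of 17 rose, adjusted p = 0.0349) passed as well, the latter not without the set-apart libraries (adjusted p = 0.201). Of 3 fibroblast markers tested none was called alone by limma, yet the list passed (median 0.13, adjusted p = 0.0215) at low levels, COL1A1 being at 0.935 TPM.

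Untreated knockout monocytes were compared with WT to see how each genotype differs without a stimulus. The labels do not say whether a genotype is a clone or a pool. Effects of a clone or a cell stock therefore cannot be told apart from those of the edit. IRF3 knockout cells (n = 3) had 151 genes higher and 183 lower, including VCAN, a proteoglycan gene, at 131 ± 27.7 TPM against 8.44 ± 4.995 TPM (3.92, adjusted p = 4.04e-10, limma), and UNC13D, which acts in granule release, at -4.11. Of 46 interferon-stimulated genes 13 were lower (21 adjusted over the list alone, median -0.90, adjusted p = 0.0385, and 0.0501 with scaling), among them IFIT1, listed at 0 in all 3 knockout libraries, and MX1 (-2.65), a call that ended when any of WT replicates 1, 2 and 3 or any knockout replicate was left out. The double knockout (n = 2) had 182 higher and 168 lower, with VCAN at 3.96, UNC13D at -4.16 and IFIT1 at -3.26 (not called without knockout replicate 1). Its total of 350 was 88 without knockout replicate 1 and 1964 without replicate 2. IRF9 knockout cells (n = 3) had 29 genes higher and 66 lower, with OAS1 (-2.37) and MX1 (-3.01, adjusted p = 0.0481) lower, the latter call ending under 9 of 12 alternatives. Their total of 95 was 62 without knockout replicate 1 and 151 without WT replicate 4. Of 46 interferon-stimulated genes 7 were lower there (15 adjusted over the list alone), and the list did not pass (median -0.87, adjusted p = 0.0535). The replicate numbers pair these libraries with those of WT. With a replicate block 50 genes were higher and 127 lower. The list then passed (median -1.24, adjusted p = 0.00148), as did IFIT1 (-2.50, adjusted p = 0.0267). The block also takes out WT replicate 4, so these values do not separate pairing from its removal. Leaving out that library alone gave the same list median of -1.24. The interferon-stimulated lists of the IRF1 (-1.003, adjusted p = 0.0674), IFNAR2 (-0.90, adjusted p = 0.09) and double knockouts (-0.76, adjusted p = 0.119) did not pass.

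IRF1 knockout cells (n = 2) had 273 genes higher and 356 lower (331 in all without knockout replicate 1), with CYP1B1 at 4.49, VCAN at 3.27 and the calprotectin gene S100A9 at 3.25, and with IRF7 lower (-1.93, adjusted p = 0.0259), not called without WT replicate 2 or 3 or either knockout replicate. Their MHC class I list (1 of 17 lower, 2 adjusted over the list alone, median -0.55, adjusted p = 0.0164) and cholesterol list (3 of 20 lower, median -0.56, adjusted p = 0.0211) passed. IRF2 knockout cells (n = 2) had 208 higher and 314 lower (236 and 226 with scaling), with SOCS1, a cytokine signalling inhibitor, at 4.04, the metallothionein gene MT2A at 3.88 and the ISG15-conjugating enzyme gene UBE2L6 at -3.32. SOCS1 was not called without either knockout replicate or against WT replicate 4 alone, nor was MT2A against that library (adjusted p = 0.0574). Of 46 interferon-stimulated genes 16 were lower (26 adjusted over the list alone, median -1.45, adjusted p = 0.0385, and 0.0746 with scaling), while against WT replicate 4 alone the list was at 0.0517 (adjusted p = 0.85), and the MHC class I list passed (median -0.49, adjusted p = 0.0173). WT replicate 4 resembled these cells, with a correlation of 0.879 to IRF2 knockout replicate 2. The total of 522 genes was 52 and 66 without knockout replicates 1 and 2, 178, 245 and 179 without WT replicates 1, 2 and 3 and 1504 without WT replicate 4, and against replicate 4 alone 9 were higher and 5 lower. IRF8 knockout cells (n = 2) had 129 higher and 246 lower (188 in all without knockout replicate 1), with the surface receptor gene CD93 at -5.74, CCR2 at -4.42 and the defensin gene DEFA4 at 3.01. Their sensing list passed (median -0.38, adjusted p = 0.039), and not with scaling (adjusted p = 0.267). IFNAR2 knockout cells (n = 2) had 40 higher and 91 lower (45 in all without knockout replicate 2), with SDC2, a syndecan gene, at -2.73, and IRF5 knockout cells (n = 2) 5 higher and 18 lower (9 and 10 in all without knockout replicates 1 and 2 and 62 without WT replicate 4), with PSTPIP2 at -3.04. IRF7 knockout cells (n = 2) had 4 higher and 3 lower (2 in all without either knockout replicate and 13 without WT replicate 4), with CD93 at -4.48 and MS4A6A at -1.76, the latter not called without either knockout replicate.

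Shared calls were counted between responses. IFNB1 protein and cGAMP in WT monocytes, which have separate controls, shared 114 higher genes against 12.4 for independent lists, and 8 lower genes against 1.1. IFNB1 protein and LPS in monocytes share their 4 control libraries. Their overlap was 40 higher genes, with 9.7 for independent lists, a mean of 0 for simulated unchanged groups against the same controls, and 25 to 35 with the controls split. LPS in monocytes and in macrophages shared 215 higher genes against 11.2, and 194 lower genes against 19.5.

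Markers of other cell types were low. The highest value over all 117 libraries was 2.71 TPM for T cell markers (CD3G), 0.496 TPM for erythroid markers (HBA1), 3.09 TPM for fibroblast markers (COL1A1) and 11.4 TPM for epithelial markers (KRT18). The B cell factor gene PAX5 was at 47.8 TPM in the library with IFNB1 protein for 24 h. The epithelial list, 2 genes tested, was called lower in untreated IRF1 (median -1.18), IRF7 (-1.13), IRF8 (-1.41) and IFNAR2 (-1.24) knockouts and higher in the IRF5 knockout (1.10).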

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

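All tests of explanations in this part were chosen only after the result was seen, apart from the interaction tests, the counts of sample splits and the test for a library far from its group, which were planned.

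Untreated WT monocytes are the group of 4 in which a library far from the others was looked for, in 28 items, and chance alone marks about 1 in 20. In 4 items the gap between 1 library and its nearest neighbour was over the critical value as a share of the range: IFNL1 in replicate 1 (1), MX1 in replicate 4 (0.838), IRF8 in replicate 3 (0.878) and the median of the MHC class I list in replicate 2 (0.836). They fall in 4 different libraries. On the log2(TPM + 1) scale IFNL1 was at 0.37 in replicate 1 and 0 elsewhere, so any value above 0 would give a ratio of 1. IRF8 ran only from 8.7 to 9.03, so its flag rests on a small range.

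The cGAMP response differed between the IRF3 knockout and WT for 785 genes and for the interferon-stimulated (-2.79), interferon (-0.80), guanylate-binding protein and CXCR3 chemokine (-1.95) and stress response lists (0.58). Against the IRF9 knockout 6 genes and the interferon list (-0.74) differed. The response to IFNB1 protein differed for 2 genes and the guanylate-binding protein and chemokine list (-0.67) in the IRF3 knockout, and for 38 genes, the interferon-stimulated list (-2.22) and the guanylate-binding protein and chemokine list (-0.95) in the IRF9 knockout. LPS responses of macrophages and monocytes differed for 109 genes and for the guanylate-binding protein and chemokine list (0.93).

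Other splits of the same libraries were fitted with limma. For digitonin 1 of 35 splits, the real one, gave as many genes (658, highest other 331), a share under 0.05 with no adjustment for the other split tests. The splits cannot tell the treatment from anything else that differs between the 2 groups of libraries. For the IRF3 knockout against WT 1 of 35 also gave as many genes (334, highest other 163), a share under 0.05 if the libraries were not paired. As the numbers pair these libraries, only the 8 splits that part as many pairs compare like with like (highest other 160), and they are too few for a share under 0.05. For the IRF9 knockout against WT 2 of 35 gave as many genes (95 genes, the other 147 with WT replicates 1, 2 and 3 against the rest), so chance is not excluded. That other split keeps the 3 knockout libraries together and moves only WT replicate 4, a set-apart library, to their side. The numbers pair these libraries too, and the 8 splits that part as many pairs are again too few for a share under 0.05. For cGAMP in WT (1422, highest other 1) and in the IRF3 knockout (23, highest other 1) the 10 splits, of which 1 was as large in each, are too few for a share under 0.05. For the difference between those responses 11 of 100 splits gave as many genes (785, highest other 2412), and chance is not excluded by these splits. Moving genotype labels within a treatment can turn the difference between genotypes into the contrast. Whether this made the splits with so many genes was not tested. Moving whole replicate pairs, chosen after that, gave 785 for the real split and at most 1 gene in the other 9 of 10.

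A first pattern is that 4 WT libraries have an IRF2 knockout library as their nearest relative: untreated monocyte replicate 4 (correlation 0.879), monocyte LPS replicate 2 (0.833), macrophage replicate 2 (0.739) and macrophage LPS replicate 2 (0.764). Mislabelled IRF2 knockout libraries are argued against by IRF2 itself, which is higher in the knockout by 1.127 as a mean over the 4 conditions (SD 0.544). A batch shared with the IRF2 knockout libraries and a different THP1 stock cannot be told apart. The differences of these libraries from other WT libraries correlate with a median r of 0.483 over the 6 pairs of conditions, but the libraries were found by their likeness to the same knockout over the same genes, so this value supports neither. For the stock the same limit holds for 2 genes, IL12RB2 and MAGED1, absent from these and the IRF2 knockout libraries and present in the other WT libraries (0 in 100 random choices of 4 WT libraries). Among libraries of other knockouts IL12RB2 ran from 7.146 to 92.844 TPM and MAGED1 from 0 to 41.226 TPM. No biological explanation was tested.

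A second pattern is that more genes fell than rose with cGAMP in WT (862 and 560), which turned with median-of-ratios scaling (525 and 673), so the excess of falls depends on the scaling. The genes called higher went from 1.48 to 9.66% of all TPM, which predicts a shift of -0.125 for every other gene, 95.6% of the median change of all genes (-0.131), so composition may account for the shift of the median. The 862 genes had a median change of -0.308 in the IRF3 knockout and -1.298 in the IRF9 knockout. A fall that needs IRF3 would give such values. The genes were chosen for their fall in WT (median -1.367), which favours a weaker value elsewhere, although the IRF9 knockout stayed near it. Of the 862, 278 were called by limma as having a higher response in the IRF3 knockout than in WT. For the others a need for IRF3 was not shown gene by gene.

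Another pattern is the set of 100 genes that rose with IFNB1 protein in the IRF9 knockout. Residual WT cells in the culture would restore each list to the same share of its WT rise, but the guanylate-binding protein list reached 25.31% (15 members) and the interferon-stimulated list 3.2% (41 members), a ratio of 7.9, which argues against them. In the IFNAR2 knockout the same genes had a median change of 0.131, 7.9% of the 1.653 in the IRF9 knockout. Signalling that needs IFNAR2 but not IRF9 would give such a low value. The genes were chosen for their rise in the IRF9 knockout, which favours a lower value elsewhere, although their median change in WT was 1.737. The IFNAR2 knockout library also still responded in the interferon-stimulated list (median 0.79, 17 of 46 genes higher by at least 1). The IFNAR2 values rest on 1 library, and the explanation stays a hypothesis.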

How the results depend on the processing

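The settings without the 4 set-apart WT libraries and against 1 of them alone were chosen after seeing the data, and the other alternatives before. Of 298 alternative values of 24 counts of genes 221 stayed within 1.5 times the reported count. Of 424 for the interferon-stimulated list comparisons 343 were counted as unchanged. With a test, unchanged means the same direction and side of the threshold. Without a test, with 1 library on each side, it means within 0.5851 of the reported value. Direction was not checked there unless the reported value was called. Of 1970 for 154 named gene changes 1735 kept their direction and side of the threshold. Of the rest, 179 lost and 11 gained a call and 45 changed sign, none of them called. Of 360 list tests, 59 called, the pseudocount ended 2 calls and made 2, scaling 11 and 4, the block 4 and 10, and leaving out the set-apart libraries 3 and 27. Where not said otherwise, the cause was not tested.

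With a pseudocount of 0.5 the difference between the IRF3 knockout and WT in the response to IFNB1 protein was called for 0 genes by limma (185 at an unadjusted p under 0.05 in the reported model), with scaling for 1 and without the set-apart libraries for 5. Without the filter the difference between the IRF9 knockout and WT with cGAMP was called for 10 genes, and with scaling LPS in monocytes gave 826. With the replicate block LPS in monocytes gave 1928, macrophages against monocytes in LPS response 232, and the untreated knockouts 1895 (IRF2), 68 (IRF5), 15 (IRF7), 177 (IRF9) and 223 (IFNAR2), and 17 of 52 list comparisons passed. Of these only the IRF9 knockout holds 3 pairs and was called paired by its numbers. The block also takes out untreated WT replicate 4, so these counts do not separate pairing from its removal. With 2 pairs each the correlations were 0.543 to 0.699 (IRF5), 0.512 to 0.653 (IRF7) and 0.51 to 0.595 (IFNAR2). For the IRF2 knockout they were 0.002 and 0.066, and for LPS in monocytes -0.465 and 0.293. In the 4 comparisons called paired by their numbers, the block changed no other call of a list or named gene than those given in the report. Without the 4 set-apart libraries the same results were 2377, 294, 1601, 121, 27, 198 and 223, with 16 of 27 list comparisons, and through the pooled spread alone cGAMP in the IRF3 knockout gave 35 genes and the IRF9 difference with cGAMP 16. Against WT replicate 4 alone the IRF2 knockout gave 14 genes, and its interferon-stimulated list was at 0.0517 (adjusted p = 0.85), the 1 list comparison past the threshold that changed sign.

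Changes of sign in results that were not called were these, in the settings with a test. With scaling the interferon-stimulated list was at 0.0453 (IRF8 knockout with cGAMP) and 0.00244 (untreated IRF3 knockout macrophages), IFNB1 with IFNB1 protein at 0.00205 and IFIT1 with LPS in monocytes at 0.1216. With the block the list was at -0.2143 (untreated IRF5 knockout) and -0.2356 (IRF7), IRF1 at 0.089 (IFNAR2 knockout) and 0.0933 (digitonin, also in the model of the compared groups), IFIT1 with IFNB1 protein in the IRF9 knockout at -0.0207, and IFNB1 in macrophages against monocytes at -0.1172 (-0.00499 in the model of the compared groups). Without the set-apart libraries the list was at -0.1997 (IRF5) and -0.1806 (IRF7), IRF1 at 0.0935 (IFNAR2 knockout) and 0.0933 (digitonin) and IFIT1 with LPS at 1.3158. Leaving out 1 library gave ranges for the list of -0.1997 to 0.5777 (IRF5), -0.1806 to 0.5068 (IRF7) and -0.5557 to 0.0753 (IRF8) in untreated monocytes, and with cGAMP -0.4254 to 0.0386 (IRF1) and -0.1118 to 0.297 (IRF2). For genes they were, in untreated knockouts, IRF1 -0.0295 to 0.6119 (IRF1 knockout) and -0.3179 to 0.0935 (IFNAR2), TNF -0.5601 to 1.2896 (IFNAR2), IRF7 -0.3962 to 0.2559 (IRF7) and IRF9 -0.4602 to 0.1254 (IRF9). With digitonin IRF1 ran from -0.3181 to 0.0933 and MX1 from -1.5188 to 0.2069, with cGAMP TNF from -0.0254 to 0.937, with LPS in monocytes IFIT1 from -2.5483 to 2.1912, with IFNB1 protein IFNB1 from -0.1766 to 0.1729 and, in the IRF9 knockout, IFIT1 from -0.1334 to 0.1897, and in macrophages against monocytes IFNB1 from -0.1766 to 0.1926. In the IRF9 knockout minus WT, IRF1 ran from -0.5042 to 0.4844 with IFNB1 protein, and with cGAMP IL1B from -0.6779 to 0.277 and IRF2 from -0.6252 to 0.00929. Settings left with 1 library on each side had no test, and there the interferon-stimulated list changed sign too. Over all settings it ran from -0.3937 to 0.0913 with IFNB1 protein (IRF7). With LPS in monocytes it ran from -1.7906 to 0.568 (IRF1), -2.0061 to 0.409 (IRF2), -0.9881 to 1.3834 (IRF8) and -2.3271 to 0.0715 (IRF9). In macrophages it ran from -0.0755 to 0.0971 (IRF7, untreated), -0.5118 to 0.1979 (IRF2, LPS) and -0.6538 to 0.2015 (IRF7, LPS).

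A model of the compared groups only has fewer libraries to estimate the spread from. With a block as well, a library whose number has no partner in the other group is fitted exactly. Few residual degrees of freedom then remain, so a low count can come from that alone. It gave 102 genes for IFNB1 protein, 393 for digitonin, 178 for LPS in monocytes, 1844 for macrophages against monocytes and 0 for LPS in macrophages by limma. For LPS in macrophages the reported model has 2701 at an unadjusted p under 0.05. With a block as well it gave 0 for IFNB1 protein, 156 for digitonin, 0 for LPS in monocytes, 6 for LPS in macrophages and 0 for macrophages against monocytes (1581, 4713 and 6024 at an unadjusted p under 0.05 in the reported model for the 3 counts of 0).

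Leaving out 1 library at a time gave these ranges, lowest and highest library named. LPS in monocytes ran from 861 (LPS replicate 1) to 2122 (LPS replicate 2), LPS in macrophages from 440 (LPS replicate 1) to 1340 (LPS replicate 2), and their difference from 98 (untreated monocyte replicate 1) to 243 (macrophage LPS replicate 2). cGAMP in the IRF3 knockout ran from 7 (cGAMP replicate 1) to 21 (cGAMP replicate 2), and the IRF9 difference with cGAMP from 1 (knockout digitonin replicate 1) to 18 (WT cGAMP replicate 3). IFNB1 protein ran from 106 (treated replicate 2) to 162 (untreated replicate 3) in the IRF3 knockout and from 51 (treated replicate 1) to 95 (untreated replicate 1) in the IRF9 knockout. Its difference from WT ran from 0 by limma (treated knockout replicate 1) to 24 (WT treated replicate 2) for IRF3 and from 14 (treated knockout replicate 1) to 47 (WT untreated replicate 3) for IRF9. The untreated knockouts ran from 331 (knockout replicate 1) to 675 (WT replicate 1) for IRF1, from 88 (knockout replicate 1) to 1964 (knockout replicate 2) for the double knockout, and up to their value without WT replicate 4 for the rest: 52 to 1504 (IRF2), 9 to 62 (IRF5), 2 to 13 (IRF7), 188 to 398 (IRF8) and 62 to 151 (IRF9), each lowest without knockout replicate 1, and 45 to 178 (IFNAR2), lowest without knockout replicate 2. The list comparisons that passed ran from 5 (without WT replicate 1, 2 or 3 or either IRF2 knockout replicate) to 14 (without WT replicate 4).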

Other observations

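The values here were chosen only after they were seen, and no test was run on them.

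WT monocytes treated with IFNB1 protein for 24 h (1 library) had all 46 interferon-stimulated genes higher by at least 1 than untreated cells, with a median change of 4.24. MX1 was at 2230 TPM, IRF1 at 29.2 TPM and CXCL10 at 18.9 TPM there, against 799, 313 and 164 TPM in the 2 libraries without a stated time. The libraries labelled 1x and 100x had list medians of 2.40 and 2.71.

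TNF with cGAMP was at 779 TPM in the double knockout and 843 TPM in the IRF1 knockout, 1 library each. With digitonin alone these were at 98.8 and 382 TPM. IL1B after LPS in macrophages was at 17360 TPM in the IRF3 knockout, 18960 TPM in the double knockout and 14270 TPM in the IRF1 knockout, from 1145, 7342 and 1907 TPM in their untreated libraries.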
